A study of Mus musculus with 6 samples.

How the data were processed

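Poly(A) RNA was sequenced from 6 cultures of RAW264.7 cells, a mouse macrophage-like line. Per the labels' protocols, 3 cultures came from a stable line carrying a doxycycline-inducible construct for HA-tagged NUR77, and 3 from a stable line carrying the same kind of construct for GFP. Each replicate was grown in its own dish and treated with doxycycline at 1 µg/mL for 18 hours, starting 24 hours after seeding. Strand-specific libraries were made from 1000 ng of total RNA with 12 PCR cycles and sequenced in a pool of 13 libraries, of which 6 were analysed here. All 6 samples were grouped by the transgene in their titles. Each group therefore holds 1 stable line, and no library of cells without doxycycline was analysed here.

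The authors deposited log2 values, 1 column per library and without pooling, for 23154 Ensembl mouse gene identifiers. Per the submitters' processing notes, TopHat2 2.1, HTSeq and DESeq2 were used with the mm10 build; the role of each tool, the strand setting of the counting and the annotation release are not given in the sources used here. From the values themselves, each deposited log2 value was the log2 of a normalized read count plus 1. After the log was undone, the values of each library summed to 10000000. Every value was a whole multiple of 1 step per library, so that whole reads could be recovered for 100% of the values within a tolerance of 0.1 read. The unit used below, normalized reads, is therefore the number of reads of a gene per 10000000 reads counted on genes. The deposited scaling sets equal totals, so a few abundant genes that differ between groups shift all other genes slightly. The table of the whole series held the same values as the per-library files, with a largest difference of 0.

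The recovered depth was 14350490, 15929487 and 15299884 reads in GFP replicates 1, 2 and 3, and 11199468, 14354453 and 12569310 reads in NUR77 replicates 1, 2 and 3. One read was worth between 0.6278 and 0.8929 normalized reads. A group with no read in any of its 3 libraries was assigned a limit of 3 reads over the group, which is 0.658 normalized reads for GFP and 0.787 for NUR77. For genes with 1 to 3 reads in a group, the ratio of summed reads is given with an exact 95% binomial interval. Such limits and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

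Identifiers were matched to the GENCODE mouse annotation of the GRCm38 (mm10) assembly, which named 22872 of them and left 282 without a name. Coordinates are from this annotation. No read was found in any library for 4547 genes. Because reads shared by near-identical copies may be split or dropped in counting, some genes with such copies are called uncertain where they are named. This marking is not complete, and an unmarked gene can have such copies too.

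The main test was limma 3.58.1 in R 4.3.3 on log2(normalized reads + 1), with a mean-variance trend and robust variance moderation, on all 6 libraries and without covariates. Genes with a mean of 10 or more normalized reads over the 6 libraries were tested, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Every adjusted p below is from this fit unless another test is named. Fold changes are NUR77 over GFP on the log2(value + 1) scale, which understates the change of low genes. Values are means ± SD over 3 libraries per group.

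Before the data were examined, 36 gene lists with 842 entries were fixed, covering macrophage, inflammatory, metabolic, mitochondrial, stress and cell cycle genes and markers of other cell types. Of these, 32 lists had 3 or more tested members and were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The lists share 23 tested genes that belong to 2 or more of them. Chromosome positions were examined as the median log2 fold change in windows of 25 neighbouring tested genes, against 1000 random orders of the genes.

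The genes named in the text were set by a rule fixed before the data were examined. It takes the 3 NR4A genes, and up to 4 changed and up to 2 unchanged members of each list. It also takes the 12 largest rises and 12 largest falls among eligible genes. Eligible genes passed the threshold, had a mean of 50 or more in the higher group and no overlap between groups. Predicted genes and pseudogenes were not eligible. Last come the isocitrate and succinate dehydrogenase genes and 5 cytokine or effector genes, chosen to reflect the topics of the series title. Not every gene that the rule allows is printed. Genes named outside the rule are stated as such.

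The alternatives were pseudocounts of 0.5 and 5, no filter and a filter at a mean of 50, TMM, total-sum and upper-quartile scaling, limma without trend, a replicate block, each library left out in turn, the other list tests, and windows of 50 genes or of genes with a mean of 50 or more. Median-of-ratios scaling and limma-voom on the recovered reads were added after seeing the data. The count tests edgeR and DESeq2 had been planned on recovered reads and were not run; limma-voom is the only test run on those reads. The fit was tested on simulated reads with the depths and means of these 6 libraries for the comparison of NUR77 with GFP, with 11194 genes tested. It recovered 31 of 50 genes changed by 1.2-fold and 44 of 50 changed by 1.5-fold. At 2-fold and at 4-fold it recovered 50 of 50, and it called 8 of 10994 unchanged genes. Most simulated genes were thus unchanged, whereas 66.7% of the tested genes were called in these data, so recovery here can differ. Simulated genes of similar level were given the same spread between libraries. Genes with a larger spread of their own were not simulated, so false calls can be more frequent in these data. Of 30 simulated lists without a change 0 were called. Simulated genes were drawn independently of each other, so this could not show how the preset correlation handles lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.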

Results

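Gene expression was measured by RNA sequencing in 2 stable lines of RAW264.7 cells, a mouse macrophage-like cell line, after 18 hours of doxycycline. One line carried a doxycycline-inducible construct for HA-tagged NUR77, a nuclear receptor encoded by Nr4a1. The other carried such a construct for GFP as control, with 3 separate dishes per line. By its title, the series addresses how NUR77 affects mitochondrial metabolism and the inflammatory response of macrophages. The labels name no inflammatory stimulus. Depth ranged from 11199468 to 15929487 reads counted on genes per library. Levels are given as normalized reads, meaning reads per 10000000 reads counted on genes, and 11201 genes were tested.

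Nr4a1 (ENSMUSG00000023034, chromosome 15, 101254269 to 101274795 on the plus strand, mm10) was measured at 170, 148 and 161 normalized reads in the GFP libraries and at 288, 314 and 297 in the NUR77 libraries. The means were 160 ± 11 and 300 ± 13.2 (SD, n = 3 per line), a rise of 1.87-fold (log2 fold change 0.90, SE 0.08, limma adjusted p = 5.5e-08). Nr4a3, a related receptor, rose from 14 ± 2.06 to 33.7 ± 3.86 normalized reads (log2 fold change 1.21, adjusted p = 9.2e-05). Nr4a2, the remaining member of the family, fell from 88.7 ± 10.7 to 67.0 ± 10.2 (log2 fold change -0.40, adjusted p = 0.019). This last call was lost without GFP replicate 1 (adjusted p = 0.1) and without NUR77 replicate 1 (adjusted p = 0.09). The list of the 3 NR4A genes was not called by camera (adjusted p = 0.49). The values do not separate reads of the transgene from those of the endogenous Nr4a1 gene, and the species of the NUR77 sequence is not given in the sources used here. Reads of a sequence that differs from the mouse gene would be undercounted on mm10, so the 1.87-fold rise and the rank that follows can be too low as a measure of total NUR77 transcript. Among the tested genes, Nr4a1 ranked 1780 by the size of its log2 fold change.

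The NUR77 line differed from the GFP line in 7475 of the 11201 tested genes (66.7%), of which 4305 rose and 3170 fell. Changes of 2-fold or more were found in 1553 genes, 860 higher and 693 lower. Under TMM scaling 3624 genes rose and 3816 fell, so which direction was more frequent rests on the scaling. The count at 2-fold or more was 2642 without a filter and 1027 with a filter at a mean of 50. In 7910 tested genes (70.6%) the 3 values of one line did not overlap the 3 of the other, where chance gives 10%. The first principal component held 93.8% of the variance and separated the lines. Pearson correlations of log2 values across genes were between 0.9929 and 0.9960 within a line and between 0.8891 and 0.8936 across lines. No pair of replicates was a duplicate, as the chi-square per degree of freedom within a line was 2.48 or more. Because each group is 1 stable line, differences between the lines cannot be separated from the effect of the transgene. The p-values measure the spread between dishes of 1 line.

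**Figure D1:**
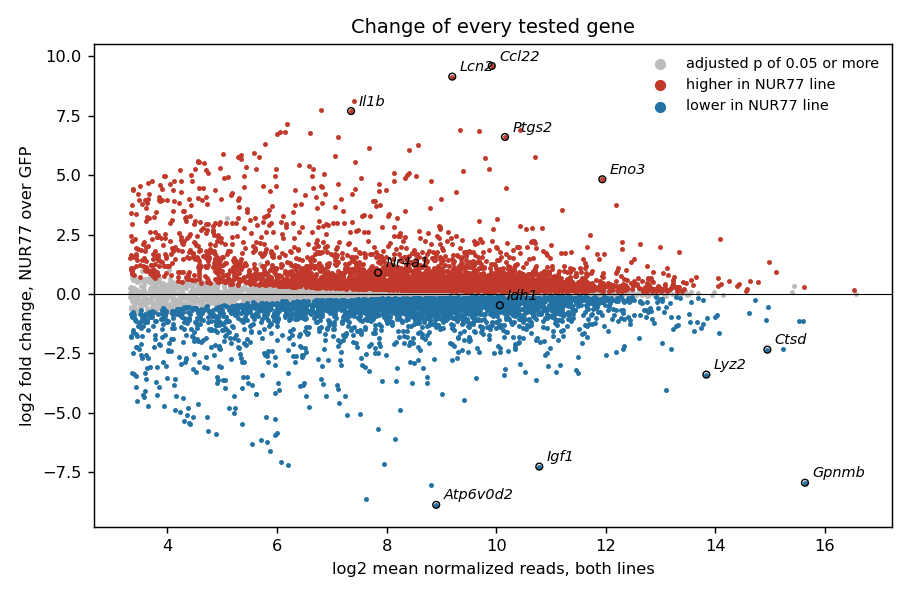
Log2 fold change of NUR77 over GFP (vertical axis) against the log2 mean normalized reads of both lines (horizontal axis) for the 11201 tested genes. Each point is 1 gene, red where it was higher and blue where it was lower in the NUR77 line at an adjusted p under 0.05, and grey otherwise; 12 genes are circled and named. Nr4a1, at 0.90, which can be too low if transgene reads were undercounted, lies inside the range, which reaches 9.60 for Ccl22 and -8.87 for Atp6v0d2.

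The 12 largest rises were led by Ccl22 and Lcn2. Ccl22, a chemokine (chromosome 8, 94745590 to 94751699), rose from 1.32 ± 0.0698 to 1935 ± 808 normalized reads, a log2 fold change of 9.60 (SE 0.29, adjusted p = 1.2e-09). Lcn2, an iron-siderophore-binding protein, rose from 1.09 ± 0.338 to 1174 ± 61.5 (log2 fold change 9.15, adjusted p = 4.5e-17). Ccr7, a chemokine receptor, had no read in the GFP line and 223 ± 80.7 normalized reads in the NUR77 line, at least 338-fold higher (3 reads over the group). Il1b, which encodes interleukin-1 beta, had 3 reads in the GFP line and 1243 in the NUR77 line, a ratio of 495 (95% interval 169 to 2405). Asb2, Ptprf and Prdm1 had 1 read each in the GFP line, with ratios of 1553 (278 to 61390), 606 (108 to 23989) and 579 (103 to 22903). Basp1 (log2 fold change 6.91), Nos2 (6.90), Ifi44 (6.88), Marcks (6.79) and Ptgs2 (6.61) completed the 12 largest rises, each with an adjusted p of 5.7e-06 or less.

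The largest falls included Gpnmb, a lysosomal and cell surface glycoprotein gene (chromosome 6, 49036546 to 49070929). It went from 101412 ± 3346 to 414 ± 58.9 normalized reads (log2 fold change -7.94, SE 0.08, adjusted p = 2.1e-15). Atp6v0d2, a subunit of the vacuolar proton pump, fell from 958 ± 91.7 to 1.09 ± 0.602 (log2 fold change -8.87, adjusted p = 4.5e-16), and Dio2, a thyroid hormone deiodinase, from 897 ± 91.9 to 2.78 ± 2.23 (-8.04). Igf1, a growth factor, fell from 3510 ± 37.7 to 22.5 ± 5.72 (-7.26). No read was found in the NUR77 line for Dkk2, Cd28 and Opcml, which were at least 502-fold, 187-fold and 170-fold lower (3 reads over the group). Ccbe1, Ccdc7a, Bach2os and Pik3c2b had 1 to 3 reads in the NUR77 line, and the GFP to NUR77 ratios were 446 (79.7 to 17641), 355 (63.3 to 14040), 142 (48.3 to 690) and 197 (54.3 to 1635). The value of Lyz1 (log2 fold change -7.15) is uncertain because of its near-identical neighbour Lyz2, as is that of Ccdc7a because of its paralog Ccdc7b. Bach2os is annotated antisense to Bach2, and the strand setting of the counting is not given.

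Of the 32 tested gene lists, 14 were called by camera at the preset correlation, 8 upward and 6 downward. With an estimated correlation 0 lists were called (5 at an unadjusted p under 0.05), with a smallest adjusted p of 0.18, while fry called 23. In the list counts below, the number of changed members adjusted over the list alone is given where it differs from that over all genes tested; elsewhere both were equal. NUR77 replicate 1 held more reads of 19 skeletal muscle genes, chosen after their values were seen, than the other libraries, 405 normalized reads against 74.5 to 96.2; without it, 7257 genes and 13 lists were called.

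**Figure D2:**
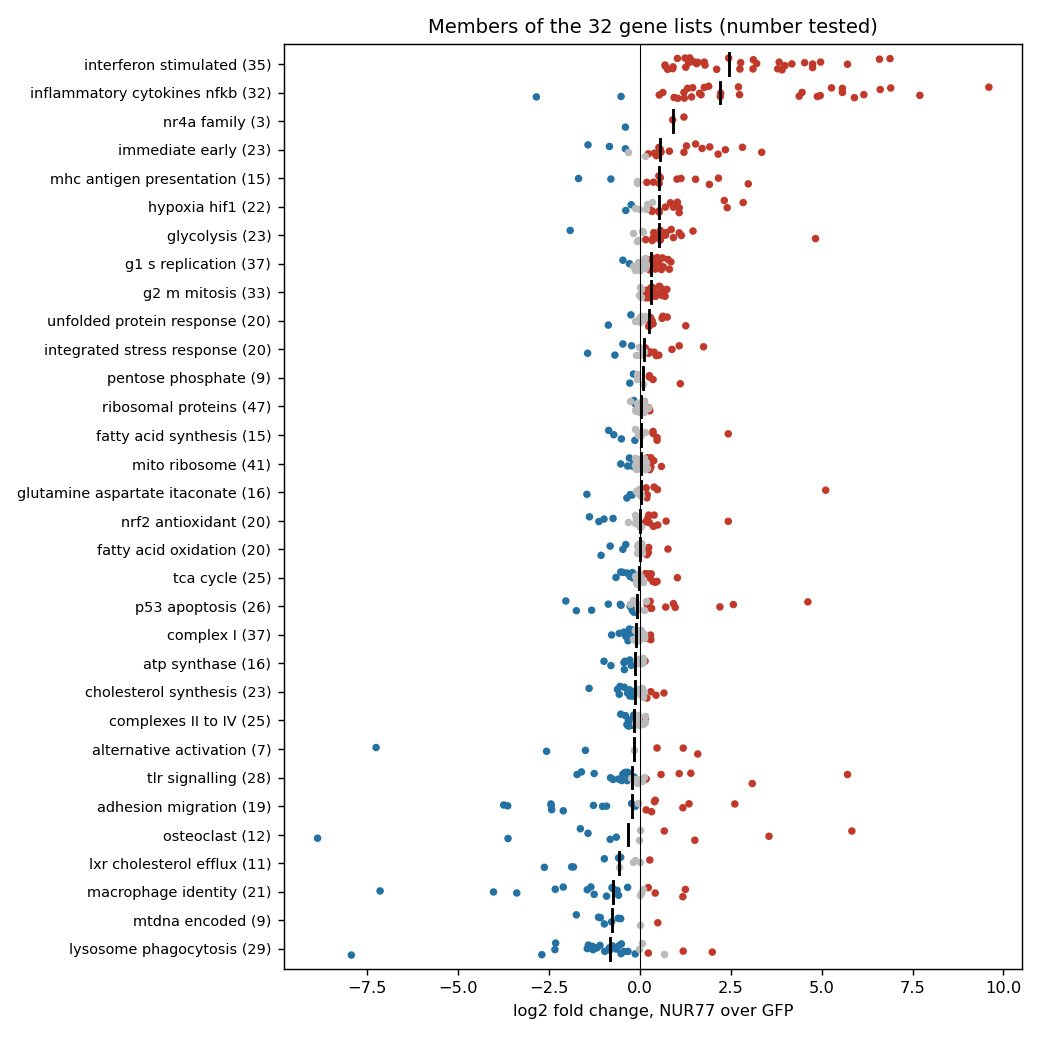
Log2 fold change of NUR77 over GFP (horizontal axis) for the tested members of the 32 gene lists (vertical axis, number of tested members in brackets). Each point is 1 gene, red or blue where it rose or fell at an adjusted p under 0.05 and grey otherwise, and each black bar is the list's median. Medians run from 2.44 for interferon-stimulated genes to -0.83 for lysosome and phagocytosis genes; those of the lists for fatty acid synthesis, glutamine, aspartate and itaconate, mitochondrial ribosome, NRF2 targets, pentose phosphate and ribosomal proteins lie near 0 and turn sign under TMM scaling.

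All 35 tested interferon-stimulated genes rose, with a median log2 fold change of 2.44 (camera adjusted p = 3.4e-13; adjusted p = 0.18 with an estimated correlation). Ifi44 rose from 13.0 ± 1.77 to 1640 ± 176 normalized reads, Irf7, a transcription factor of the interferon response, from 32.3 ± 4.78 to 1746 ± 284, Rtp4 from 2.55 ± 2.28 to 274 ± 32.8, and Mx2 from 2.27 ± 2.11 to 82.2 ± 2.72. The list of inflammatory cytokines and NF-kB targets had 30 members that rose and 2 that fell of 32 tested, with a median of 2.21 (camera adjusted p = 7.5e-10; adjusted p = 0.18 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 10.5 ± 4.84 to 1284 ± 57.9 and Ptgs2, the inducible cyclooxygenase, from 22.1 ± 3.42 to 2267 ± 421. Tnf rose from 611 ± 90.0 to 1418 ± 18.5 (log2 fold change 1.22, SE 0.09, adjusted p = 4.4e-08). Ccl2, a monocyte-attracting chemokine, rose from 4.85 ± 1.70 to 407 ± 31.9 (6.16, SE 0.19, adjusted p = 5.2e-14). Il6 had 3 reads in the GFP line and 130 in the NUR77 line, a ratio of 51.8 (95% interval 17.3 to 254). Tnf, Il6, Il1b, Nos2 and Ccl2 had been chosen because the series title concerns the inflammatory response. Each of these 5 genes was higher in all 3 NUR77 libraries than in any GFP library.

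Genes of antigen presentation rose in 11 of 15 cases and fell in 2 (median 0.53, camera adjusted p = 0.036; adjusted p = 0.7 with an estimated correlation). Cd40 (log2 fold change 2.98), H2-T23 (2.16) and Cd74 (1.91) rose, and the co-stimulatory gene Cd86 fell (-1.69). The classical class I genes H2-D1 and H2-K1 were at -0.07 and -0.09 (adjusted p = 0.23 and 0.21), and passed as lower under TMM scaling, at -0.14 and -0.17 (adjusted p = 0.02 and 0.028), and under upper-quartile (0.028 and 0.037) and median-of-ratios scaling (0.035 and 0.042). Toll-like receptor signalling genes went both ways, with 7 that rose and 14 that fell of 28 (median -0.21, mean 0.08, camera adjusted p = 0.1). Irak3 rose (3.09), and the endosomal receptors Tlr7 (-1.61) and Tlr8 (-1.73) fell; both lie in the region of chromosome X described below, where most neighbours rose. Immediate-early genes rose in 18 of 23 cases and fell in 3, or in 4 when adjusted over the list alone (median 0.56, camera adjusted p = 0.0045; adjusted p = 0.31 with an estimated correlation). Myc rose from 46.5 ± 6.95 to 481 ± 37.4 normalized reads, and Dusp5 (2.82), Fosl1 (2.35) and Zfp36 (2.15) rose as well.

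Genes of the lysosome and of phagocytosis fell in 23 of 29 cases and rose in 3, or in 4 when adjusted over the list alone (median -0.83, camera adjusted p = 8.0e-08; adjusted p = 0.18 with an estimated correlation). The proteases Ctsb and Ctsd fell from 64435 ± 529 to 12863 ± 67.0 and from 52854 ± 2075 to 10416 ± 520 normalized reads, and the Fc receptor gene Fcgr3 fell from 1076 ± 42.0 to 165 ± 9.09. Ctsc and Glb1 were at 0.06 and -0.03 (adjusted p = 0.33 and 0.68). Macrophage identity genes fell in 14 of 21 cases and rose in 4 (median -0.75, camera adjusted p = 0.0018; adjusted p = 0.18 with an estimated correlation). Mpeg1 fell from 16580 ± 261 to 1019 ± 122, Lgals3 from 15585 ± 984 to 3097 ± 143 and Lyz2, the macrophage lysozyme, from 26664 ± 848 to 2566 ± 506, with the limit given above for Lyz1. Spi1, which encodes the myeloid transcription factor PU.1, was at 0.09 (adjusted p = 0.21) and Ptprc at 0.03 (adjusted p = 0.64). Cholesterol efflux genes fell in 6 of 11 cases, or 7 when adjusted over the list alone, and 1 rose (median -0.57, camera adjusted p = 0.0045; adjusted p = 0.37 with an estimated correlation). Abcg1, a sterol exporter, fell by 1.88 on the log2 scale, Nceh1 by 2.63, Npc1 by 0.98 and Nr1h3, which encodes the oxysterol receptor LXR alpha, by 1.83; Nceh1 lies in the region of chromosome 3 described below.

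**Figure D3:**
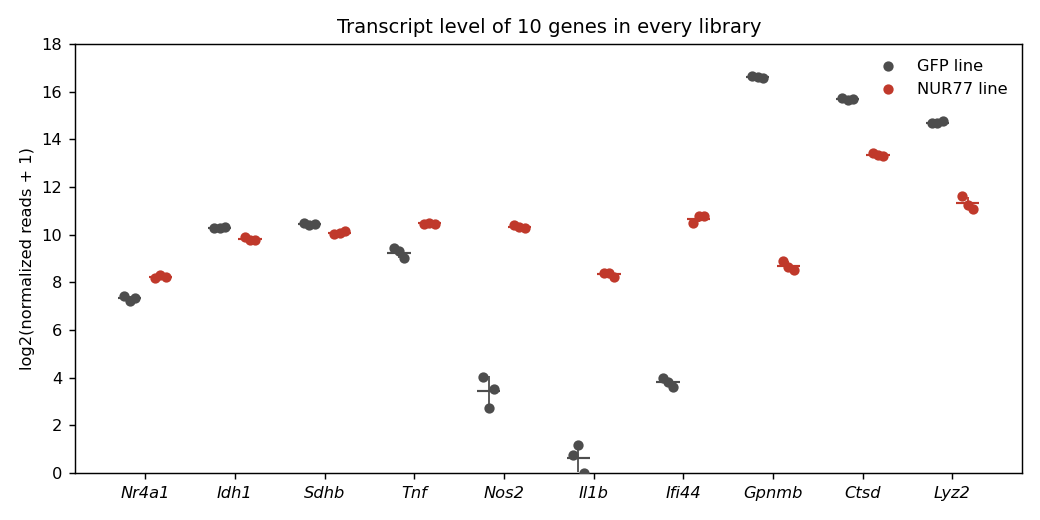
Level of 10 genes in every library, as log2(normalized reads + 1) on the vertical axis, for the GFP line (grey) and the NUR77 line (red). Each point is 1 library, horizontal bars are means and vertical bars are SDs of the 3 log2 values. Nr4a1, Tnf, Nos2, Il1b and Ifi44 were higher, and Idh1, Sdhb, Gpnmb, Ctsd and Lyz2 lower, in every NUR77 library than in any GFP library.

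In the isocitrate and succinate dehydrogenase genes, chosen because the series title concerns mitochondrial metabolism, changes were under 2-fold. Some genes of the mitochondrial lists described below changed by 2-fold or more. Idh1, the cytosolic isocitrate dehydrogenase (chromosome 1, 65158616 to 65186500, minus strand), fell from 1247 ± 20.7 to 898 ± 51.5 normalized reads (log2 fold change -0.47, SE 0.06, adjusted p = 9.9e-07). The mitochondrial isoform gene Idh2 was at 0.02 (adjusted p = 0.8), and Idh3a and Idh3b were at -0.11 and -0.07 (adjusted p = 0.061 and 0.24). Of the succinate dehydrogenase subunits, Sdhc fell from 1247 ± 54.4 to 866 ± 49.1 (-0.53, adjusted p = 4.9e-07), Sdhb from 1390 ± 28.4 to 1083 ± 55.8 (-0.36, adjusted p = 1.7e-05) and Sdhd from 1530 ± 62.0 to 1270 ± 62.4 (-0.27, adjusted p = 3.9e-04). Sdha was at -0.11 (adjusted p = 0.054). Idh3g fell by 0.19 on the log2 scale (adjusted p = 0.011), a call that was lost without NUR77 replicate 1 (adjusted p = 0.053) and without the trend (adjusted p = 0.056). Idh3a, Idh3b and Sdha passed the threshold under TMM scaling, at -0.19, -0.14 and -0.18 (adjusted p = 0.0054, 0.021 and 0.0039), and likewise under upper-quartile and median-of-ratios scaling. Sdha also passed without GFP replicate 1 (adjusted p = 0.045), and Idh3a without NUR77 replicate 1 (adjusted p = 0.029).

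The citric acid cycle list as a whole was not called, with 9 genes that rose and 8 that fell of 25 (median -0.02, mean 0.01, camera adjusted p = 0.69). Pcx, pyruvate carboxylase, rose (log2 fold change 1.03) and Suclg2 fell (-0.66); Pcx lies in the region of chromosome 19 described below, where most neighbours rose. Respiratory complexes II to IV fell in 13 of 25 cases and rose in 2 (median -0.16, camera adjusted p = 0.031; adjusted p = 0.7 with an estimated correlation). Complex I genes fell in 13 of 37 cases, or 12 when adjusted over the list alone, and rose in 3 (median -0.11, camera adjusted p = 0.04; adjusted p = 0.66 with an estimated correlation). Ndufb5 (-0.78) and Ndufs8 (-0.57) fell most; Ndufb5 lies in the region of chromosome 3 described below, where most neighbours fell. The call of complexes II to IV was lost without NUR77 replicate 3 (adjusted p = 0.083), and that of complex I without GFP replicate 3 (0.057), NUR77 replicate 1 (0.055) or NUR77 replicate 3 (0.083). The ATP synthase list was not called (median -0.14, 8 fell and 1 rose of 16, camera adjusted p = 0.067), though it passed under TMM scaling (adjusted p = 0.031), upper-quartile scaling (0.034), median-of-ratios scaling (0.037) and limma-voom (0.05), and without GFP replicate 2 (0.041) or NUR77 replicate 2 (0.049). Transcripts encoded by mitochondrial DNA fell in 7 of 9 cases and rose in 1 (median -0.78, camera adjusted p = 0.0061; adjusted p = 0.57 with an estimated correlation). mt-Cytb fell from 68663 ± 2520 to 31134 ± 2670 normalized reads and mt-Nd1 from 42297 ± 2082 to 19834 ± 1305, while mt-Co1 stood at 97482 ± 643 and 96999 ± 66.8 (adjusted p = 0.89). mt-Nd3, at 18.1 ± 2.7 and 4.97 ± 2.24, is uncertain because of copies in the nuclear genome. The same limit can apply to the other transcripts of mitochondrial DNA.

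Glycolysis genes rose in 17 of 23 cases and fell in 1 (median 0.51, camera adjusted p = 0.0045; adjusted p = 0.7 with an estimated correlation). Eno3, an enolase, rose from 265 ± 17.0 to 7579 ± 345 normalized reads, Pfkp, a phosphofructokinase, from 3116 ± 170 to 8571 ± 651, and Pfkfb3 from 545 ± 43.0 to 1205 ± 87.5. The hexokinase gene Hk3 fell from 3536 ± 292 to 932 ± 85.5, and Pkm was at 0.07 (adjusted p = 0.19). Hypoxia-response genes rose in 15 of 22 cases, or 16 when adjusted over the list alone, and fell in 2 (median 0.53, camera adjusted p = 0.02; adjusted p = 0.78 with an estimated correlation), with Adm (2.84), P4ha2 (2.40) and Ero1l (2.32) foremost and Vegfa at -0.13 (adjusted p = 0.14). Vegfa passed as lower under TMM (-0.20, adjusted p = 0.021), upper-quartile (0.033) and median-of-ratios scaling (0.032), without GFP replicate 2 (0.041) and without NUR77 replicate 3 (-0.22, adjusted p = 0.0089). Acod1, which makes itaconate, rose from 18.3 ± 1.93 to 663 ± 76.6, in a list of glutamine, aspartate and itaconate genes that was not called (6 rose and 4 fell of 16, median 0.03, camera adjusted p = 0.99). That list's median turned to -0.05 under TMM scaling. Ass1, argininosuccinate synthase, fell (log2 fold change -1.46).

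Cell cycle genes rose by small amounts. The G2/M list had 29 of 33 genes that rose and 0 that fell (median 0.31, camera adjusted p = 2.4e-04; adjusted p = 0.57 with an estimated correlation), among them Bub1 (0.74), Ube2c (0.69) and Top2a (0.63). The G1/S and replication list had 23 of 37 that rose, or 24 when adjusted over the list alone, and 2 that fell (median 0.31, camera adjusted p = 0.02; adjusted p = 0.78 with an estimated correlation), among them Lig1 (0.85), Ccne1 (0.81) and Tk1 (0.77).

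The remaining lists were not called by camera, whose adjusted p is given for each. Alternative activation had only 7 tested members of the 18 in the list, so most of its genes were not assessed. Of the 7, 3 rose and 3 fell (adjusted p = 0.5), with falls of Igf1, Klf4 (-2.57) and Tgm2 (-1.50) and a rise of the interleukin-4 receptor gene Il4ra (1.59). Osteoclast genes had 4 that rose and 6 that fell of 12 (adjusted p = 0.39), with Mmp9 (5.83) and Car2 (3.55) higher and Atp6v0d2 (-8.87) and Ctsk (-3.63) lower. Adhesion and migration had 7 that rose and 11 that fell of 19 (adjusted p = 0.097), with Itgal (2.61) higher and Itgax (-3.75), Cxcr4 (-3.64) and S1pr1 (-2.45) lower. Cholesterol synthesis had 4 that rose and 12 that fell of 23 (adjusted p = 0.088), a list that passed without NUR77 replicate 2 (adjusted p = 0.042); Insig1 fell (-1.40). The unfolded protein response had 11 that rose and 2 that fell of 20 (adjusted p = 0.31), with Herpud1 (1.26) higher and Edem1 (-0.87) lower. The integrated stress response had 9 that rose and 4 that fell of 20 (adjusted p = 0.64), with Nupr1 (1.75) higher and Atf5 (-1.44) lower. p53 and apoptosis genes had 10 that rose and 10 that fell of 26 (median -0.08, mean 0.19, adjusted p = 0.72), with Fas (2.57) and Pmaip1 (2.20) higher and Eda2r (-2.04) lower. NRF2 targets had 9 that rose and 4 that fell of 20, or 5 when adjusted over the list alone (adjusted p = 0.86); the camera direction was downward with a median of 0.01. The ferritin genes Fth1 (-1.13) and Ftl1 (-0.99), which have processed pseudogenes and are uncertain, fell, and Me1 (2.43) rose. Fatty acid oxidation had 4 that rose and 4 that fell of 20 (adjusted p = 0.54), with Acadvl (0.77) higher and Acaa1a (-1.07) lower. Fatty acid synthesis had 5 that rose and 4 that fell of 15 (adjusted p = 0.99), with a camera direction downward and a median of 0.04. Pentose phosphate genes had 4 that rose and 2 that fell of 9 (adjusted p = 0.69), with Prps2 (1.11), which lies in the region of chromosome X described below. Mitochondrial ribosome genes had 12 that rose and 5 that fell of 41 (adjusted p = 0.96), or 10 and 5 when adjusted over the list alone. Ribosomal protein genes had 10 that rose and 3 that fell of 47 (adjusted p = 0.64), or 5 and 0 when adjusted over the list alone, and have many pseudogenes. The medians of the last 3 lists and of the fatty acid synthesis and NRF2 lists turned below 0 under TMM scaling.

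Markers of the other cell types in the fixed lists were low in both lines. Skeletal muscle genes, given above for NUR77 replicate 1, formed no list here. The 4 such lists had 0 to 2 tested members each, and their highest genes were Cd79b at 0.450 ± 0.390 and 21.9 ± 8.38 normalized reads, Col3a1 at 11.9 ± 2.34 and 27.4 ± 30.6, S100a8 at 3.91 ± 1.12 and 25.7 ± 12.9, and Esrp1 at 0 and 0.827 ± 0.90, in the GFP and NUR77 lines.

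Neighbouring genes at the distal end of chromosome X were higher in the NUR77 line. In the window from Txlng to Mid1 (chromosome X, 162778919 to 170005736, mm10), 22 of 25 tested genes rose and 3 fell, with a median log2 fold change of 1.02 and an interquartile range of 0.77 to 1.28. The 25 tested genes before it had a median of -0.00, and all genes of the analysis 0.06. None of 1000 random orders of the genes held a window as far from the median (permutation p = 1.0e-03, the smallest these permutations can give). Piga rose from 267 ± 20 to 742 ± 31 normalized reads, Hccs from 726 ± 6.13 to 1255 ± 7.07 and Prps2 from 1064 ± 27.2 to 2301 ± 92.5; Piga and Hccs were chosen after their values were seen. The 3 genes that fell were Tlr7, Tlr8 and Asb11. Of 10644 windows, 24 lay beyond the 95th percentile of the random orders, in 3 regions. On chromosome X the overlapping windows together ran from Ubqln2 to Mid1 (153498227 to 170005736, 43 genes, median 0.79, 32 rose and 9 fell). Each of these windows shares genes with the window from Txlng to Mid1. The longer run therefore does not show that the shift extends beyond that window. The other regions were on chromosome 3 (20057811 to 35856276, 26 genes, median -0.48, 19 fell and 5 rose) and chromosome 19 (3913491 to 4793901, 27 genes, median 0.58, 17 rose and 4 fell).

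**Figure D4:**
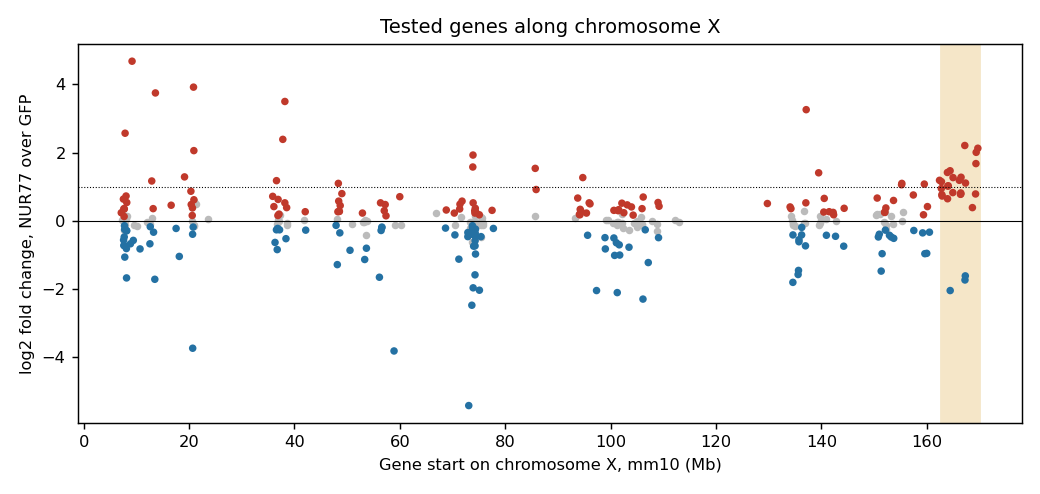
Log2 fold change of NUR77 over GFP (vertical axis) for the tested genes of chromosome X by gene start in Mb on mm10 (horizontal axis). Red and blue points rose or fell at an adjusted p under 0.05, grey points did not pass, the shaded band is the window of 25 genes from 162778919 to 170005736, and the dotted line marks a log2 fold change of 1. In the band 22 genes lie above 0 and 3 below.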

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

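Median-of-ratios scaling and limma-voom on recovered reads were chosen after seeing the data; all other alternatives were set before the data were examined. The count of changed genes stayed within 1.5 times 7475 under every alternative, from 6749 to 7257 with a library left out and up to 8429 without a filter, and 0 genes called in both the main fit and an alternative had opposite signs. The count changed by 2-fold or more moved with the filter because other genes were tested: 2642 without a filter (1403 higher and 1239 lower) and 1027 at a mean of 50 or more (558 higher). The Nr4a1 log2 fold change was 0.85 to 0.95 with a library left out and was called each time. Of the 14 lists called by camera, 0 were called with an estimated correlation, whereas fry, which asks a different question, called 23; leaving out a library gave 12 to 16 lists. The window on chromosome X kept its direction with windows of 50 genes (median 0.75) and with genes at a mean of 50 or more (0.95).

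Total-sum scaling changed nothing, since the deposited values already have equal totals. TMM, upper-quartile and median-of-ratios scaling shifted the median of all genes by -0.07, -0.06 and -0.06, and the share of changed genes that were higher from 57.6% to 48.7%, 50.1% and 50.8%, so that directions of small changes rest on the scaling. Over the named genes and lists and their alternatives, 3276 gene values and 573 list values kept their side of the threshold, 81 and 16 passed it only under the alternative, 13 and 18 only in the main fit, and none reversed; the cause was not tested. Same-numbered libraries of the 2 groups had correlations of deviations of 0.00, 0.11 and 0.04, so the numbers are not taken as pairs; the replicate block called 7585 genes, and not every library correlated best with its own number. The planned edgeR and DESeq2 fits were not run. In the simulation, where most genes were unchanged, a fold of 1.2 was recovered in 31 of 50 genes at this depth. Recovery in these data can differ.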

Other observations

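The genes and tests on V-ATPase, MiT/TFE and muscle lists were chosen after the main results were seen, as were the genes with 3 or fewer reads in one line, the scaling test, the line test, the test on muscle markers under the testing minimum and the split count for all changed genes.

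Subunit genes of the vacuolar proton pump (V-ATPase), which acidifies lysosomes, were lower in the NUR77 line beyond Atp6v0d2. Of 16 tested subunit genes outside the fixed lists, 14 fell and 1, Atp6v0a2, rose. Atp6v1c1 fell from 4623 ± 89.4 to 1457 ± 25 normalized reads, Atp6v0c from 5013 ± 106 to 2174 ± 64.9 and Atp6v1a from 9925 ± 390 to 4830 ± 135. Transcripts of the MiT/TFE factors, known regulators of lysosomal genes, fell as well. Mitf went from 765 ± 23 to 393 ± 13.6 and Tfeb from 312 ± 21.5 to 230 ± 21.9, while Tfe3 went from 973 ± 35.0 to 884 ± 52.1 (limma adjusted p = 0.044). Tfec had 41 reads in the GFP line and 0 in the NUR77 line, at least 11.4-fold lower (3 reads over the group). The median log2 fold change of the 16 V-ATPase genes was -0.68 (camera p = 1.5e-06; p = 0.032 with an estimated correlation). Lower output of these factors is a candidate explanation for the lower lysosomal genes, but the V-ATPase genes were examined after the lysosomal list had been seen to fall, and any cause of lower lysosomal genes predicts their fall. The test therefore does not decide for these factors, and the explanation stays open.

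With 300 or more reads in one line and 3 or fewer in the other, 18 genes stood far apart between the lines, 11 higher in the NUR77 line and 7 in the GFP line; 5 of them had 0 reads in the other line. Besides those named in the report they include Cd5l, a macrophage-secreted protein (0.645 ± 0.654 and 95 ± 12 normalized reads in GFP and NUR77), Lpar1, a lysophosphatidic acid receptor (0.450 ± 0.390 and 80.6 ± 5.69), Tmeff1 (0.427 ± 0.370 and 109 ± 2.08) and Rem2 (0.682 ± 0.697 and 80.4 ± 8.96).

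Inflammatory and interferon-stimulated genes were higher in the NUR77 line. The choice among the scalings used here is argued against, since the lower of the medians of both lists was 2.15 across TMM, upper-quartile and median-of-ratios scaling. These scalings shift the median of all genes by only -0.07 or -0.06, so that outcome could be foreseen. Other scalings were not tested. A direct effect of copy number in shifted regions is argued against too, as 0% of the 67 tested members lay in one. These regions hold only 26, 27 and 43 of 11130 genes, so few members would lie there by chance. Copy changes in segments shorter than a window of genes, and indirect effects of genes in these regions, were not tested and stay open. A difference between the stable lines that is unrelated to the transgene cannot be told apart from an effect of NUR77, because the design has 1 line per group and no library without doxycycline was analysed. The 1.87-fold rise of Nr4a1, which can be too low if transgene reads were undercounted, does not decide between them, and NUR77 itself, the difference that the design names, remains an untested explanation.

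The raised genes at the end of chromosome X are not explained by the chance order of genes, with 0 of 1000 random orders as far. Copy gain of the region in the NUR77 line is a candidate explanation. It predicted a ratio of 1.5 to 2.7 for genes of the region too low for the main test, and against it a ratio under 1.3. The observed ratio over 8 such genes was 1.29 (SE 0.169), with 21.8 ± 4.04 and 28.1 ± 3.65 normalized reads in GFP and NUR77. Of the 8 genes, 5 were higher in NUR77. Without the largest gene the ratio was 1.34, above the bound of 1.3. The ratio of 1.29 lies just below that bound, by less than its SE and on genes near the floor. Copy gain and regulation of the region therefore cannot be told apart.

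A set of 19 skeletal muscle genes was higher in NUR77 replicate 1, at 405 normalized reads against 74.5 to 96.2 in the other libraries. Reads of muscle cells in this library may be the source, for instance from another library of the pool, which was not tested. A test set before its values were seen, on 25 markers that had not been looked at, asked for a ratio of 1.5 or more to either of the other NUR77 libraries. It gave 1.40, under that bound, and the markers together stood at 690 normalized reads in NUR77 replicate 1 against 663 to 737 in the GFP libraries. Tnni2 alone stood at 336 to 385 in the GFP libraries and at 96.4, 58.5 and 71.6 in the NUR77 libraries. The comparison of these totals with GFP therefore says little about muscle reads. In the other libraries 94.4% of these markers' reads came from 7 genes that the cells themselves express, such as Tnni2 and Srl, so the bound could not show a small share; on the other 18, in a test chosen afterwards, the ratio was 2.23 (95% counting interval 1.58 to 3.18), while Ckm, abundant in mature muscle, stood at only 8.04 normalized reads against 4.18 and 5.57.

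Splitting the 6 libraries in other ways gives 10 splits, too few for a share under 0.05. The real split was the 1 split with as large a count in each case. It called 7475 genes, 1553 genes changed by 2-fold or more, and 14 lists, where the highest of the other splits called 0, 0 and 13 with limma and camera (up to 89 genes at an unadjusted p under 0.05). The other splits called between 8 and 13 lists each. Every other split mixes the lines and keeps part of their difference, which also widens the spread within its groups. Gene counts of 0 in those splits could thus be foreseen and do not measure chance. Whether the list calls of those splits come from the difference between the lines was not tested.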
